A study of Homo sapiens with 8 samples.

How the data were processed

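Total RNA of 8 samples of TAL1-FKBP12 Jurkat cells, 2 for each of 4 treatments of 24 hours, had been sequenced as strand-specific paired-end libraries. Per the submitters' processing notes, the authors used STAR 2.5.2a, featureCounts, DESeq2 1.12.4 and the hg19 genome. The authors deposited a table of integer counts per gene and library, with 63677 genes. They also deposited 3 tables, each of 1 treatment against DMSO. In these deposited tables the log2 fold changes and their errors were made by the authors with DESeq2 and are relative to DMSO. The score in each deposited table is the authors' fold change divided by its error, and each p-value, raw or adjusted, is also the authors'. The strand setting of the counting and the gene annotation are not given in the sources used here, so values of antisense or overlapping genes are read with caution. Near copies, such as GIMAP, histone, ribosomal protein and T cell receptor genes, can share reads. No coordinates are given, since the counts were made on another genome build than the reference used here.

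Genes were kept by edgeR's filterByExpr, which left 15646, holding at least 99.891% of the counts of each library. Counts were scaled by TMM and fitted in 1 quasi-likelihood model of the 4 groups over all 8 libraries with edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates and 4 residual degrees of freedom. The common biological coefficient of variation was 0.0804. Each comparison used a 2-sided quasi-likelihood F-test, with p-values adjusted by Benjamini-Hochberg over all genes tested and a threshold of 0.05. The 6 comparisons were each treatment against DMSO, the combination against dTAG-13, the combination against GSI, and the departure of the combination from the sum of both single effects on the log2 scale. CPM are counts scaled to library size with the TMM factors, and SD is over 2 libraries. Total counts ran from 17544319 to 22180009 per library, of which 7.8% to 8.81% were mitochondrial.

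Before the data were examined, 32 gene lists, the comparisons, the rule for named genes and the other settings to try were chosen. The 28 lists with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Alternatives were an estimated correlation, the rotation test fry, and a replicate block. Counts adjusted over the list alone used the edgeR p-values of its members. The genes named are the 8 highest and 8 lowest called genes by log2 fold change in each comparison with DMSO, among genes with a mean of at least 5 CPM whose groups do not overlap. For the other comparisons 4 and 4 were taken, with 17 fixed genes and up to 3 members of each list in each direction. Genes with clone names were left out of this rule.

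The other settings were DESeq2's size factors, no filter on low counts and the Wald test of DESeq2 1.42.0. A replicate block and a fit of the 4 compared libraries alone were also tried. So was leaving out in turn each library of the groups compared. An offset for transcript length and GC content, averages of each drug's effect over both backgrounds and a block with the DMSO numbers crossed were added after seeing the data. Overlaps against shared DMSO libraries were set beside 10 simulations of unchanged groups.

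The edgeR test of dTAG-13 against DMSO was tested on simulated data of 15345 genes in 8 libraries, 2 per group. Depths were those of the real libraries, and the simulated counts were fitted in the same model of 4 groups. Each gene's mean and spread came from all 8 libraries, not from dTAG-13 and DMSO alone. The test recovered 50.7% of genes changed 1.5-fold, 75.5% of those changed 2-fold and 92.7% of those changed 4-fold, with 7.13% false among its calls and 1 false call in 5 runs without change. In 5 runs of camera, 5 of 5 lists of 15 genes lowered by a log2 change of -0.3 were found, and 0 of 145 unchanged lists passed. Simulated genes varied independently of each other, so these runs do not show how often camera passes unchanged lists of correlated genes.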

Results

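RNA from Jurkat cells, an established human T-cell acute lymphoblastic leukaemia (T-ALL) line, was profiled by strand-specific RNA sequencing after 24 hours of treatment. The cells carried TAL1, a basic helix-loop-helix transcription factor expressed in this leukaemia, fused to FKBP12, the tag through which dTAG-13 brings a protein to the cereblon ubiquitin ligase for degradation. They received DMSO (the solvent control), dTAG-13, GSI (the usual abbreviation of a gamma-secretase inhibitor, a drug that blocks the cleavage that activates NOTCH receptors), or dTAG-13 together with GSI, named the combination here. Each of the 4 groups had 2 libraries, and the doses are not given in the labels. Total counts per library ran from 17544319 in DMSO replicate 1 to 22180009 in dTAG-13 replicate 2, and 15646 of the 63677 listed genes were expressed highly enough to be tested. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

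Replicates of a group had log2 CPM (counts scaled to library size) correlated across genes at 0.992 to 0.993, and their counts differed by more than sampling noise (chi-square per degree of freedom 4.45 to 13.4), so the 2 libraries of each group were not copies of each other. The first principal component, with 29.3% of the variance, placed the 4 libraries with GSI (9.13 to 23.7) apart from the 4 without it (-22.6 to -13.1). The second component, with 16.5%, separated replicate 1 from replicate 2 of GSI (14.3 and -18.5) and of the combination (12.6 and -20.8), and less widely of dTAG-13 (8.76 and -6.38). The DMSO libraries lay the other way (0.82 and 9.1). Markers of other cell types were low or absent: 12 myeloid markers summed to 0.366 to 0.741 CPM per library, 12 epithelial and stromal markers to 1.82 to 4.05 CPM, and 19 erythroid and megakaryocytic markers to 14.1 to 19.5 CPM, nearly all from EPOR. The 10 B-cell markers summed to 226 to 274 CPM without GSI and to 339 to 472 CPM with it, mostly from IGLL1 and CD79A, which encode parts of the pre-B and B cell receptors. CD79A rose with GSI (log2 fold change 0.59, SE 0.11, adjusted p = 0.0157) and with the combination (0.54, SE 0.11, adjusted p = 0.0338) against DMSO.

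**Figure D1:**
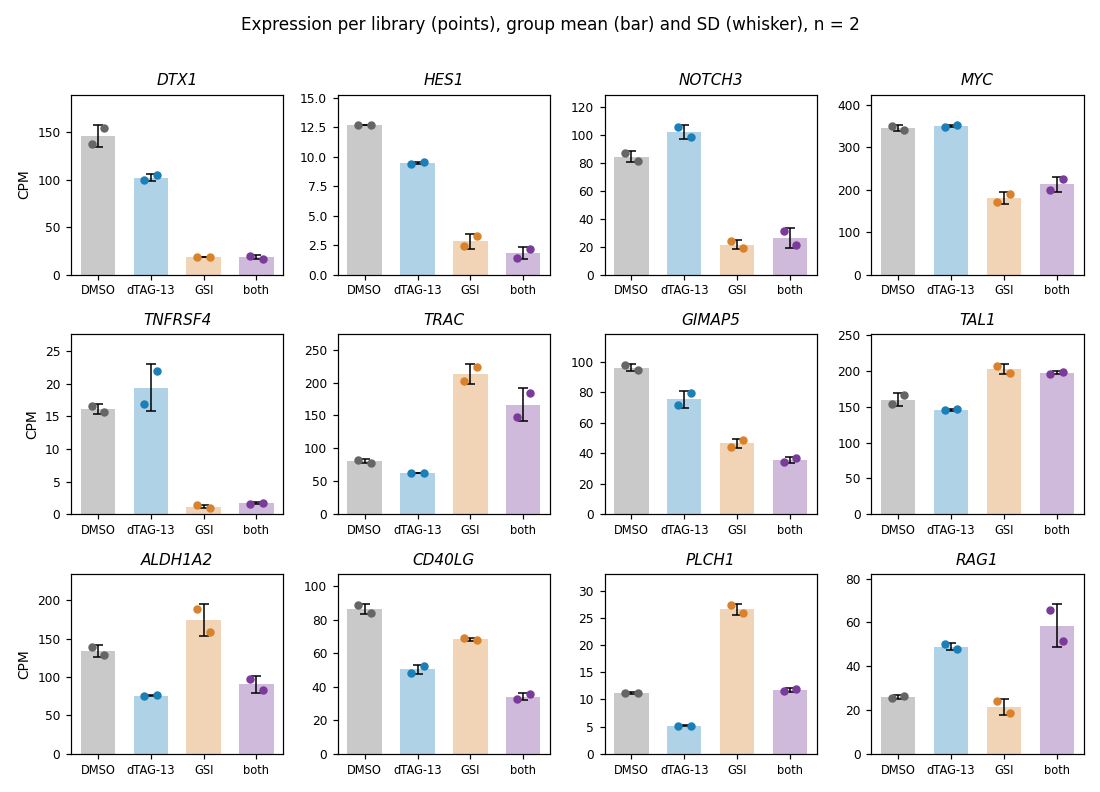
Each panel plots 1 of 12 genes in CPM on a linear axis from 0, with 1 point per library, a bar for the mean of the 2 libraries of a group and a whisker for the SD; "both" is the combination of dTAG-13 and GSI. DTX1 stood at 146 CPM with DMSO and at 18.6 CPM with GSI, while CD40LG and ALDH1A2 were lower with dTAG-13 than without it whether or not GSI was present.

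The comparison of dTAG-13 with DMSO asks which transcripts respond to removal of the tagged TAL1 protein. PLCH1, which encodes a phospholipase C, fell from 11.2 ± 0.098 CPM with DMSO to 5.17 ± 0.0554 CPM with dTAG-13 (mean ± SD, n = 2), a log2 fold change of -1.11 (SE 0.13, adjusted p = 0.00856). CD40LG, the ligand that activated T cells present to CD40, fell from 86.5 ± 3.18 to 50.5 ± 2.81 CPM (-0.78, SE 0.09, adjusted p = 0.00856). ALDH1A2, a retinaldehyde dehydrogenase reported as a TAL1 target in T-ALL, fell from 134.2 ± 7.88 to 75.9 ± 0.564 CPM (-0.82, SE 0.11, adjusted p = 0.0253). These were the calls of edgeR's quasi-likelihood test over the filtered genes of all 8 libraries, with 3 genes lower and 0 higher. In that test 601 genes, 3.84% of those tested, had an unadjusted p below 0.05, a share that unchanged genes alone could give. That test pools the spread of all 4 groups. Replicates differed more with GSI and the combination (chi-square per degree of freedom 13.4 and 12.6) than with DMSO and dTAG-13 (4.45 and 5.92). The pooled spread may be too wide for this comparison, so the share does not show that few genes changed. DESeq2 called 18 lower and 3 higher. The same edgeR test called 40 lower and 11 higher without the filter on low counts, and 59 lower and 12 higher in a fit of the 4 compared libraries alone. The TAL1 transcript, 160 ± 9.04 CPM with DMSO and 146 ± 1.24 CPM with dTAG-13, had a log2 fold change of -0.13 (SE 0.08), and TAL1 protein was not measured in these data.

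Among gene lists fixed before the data were examined, all 12 genes reported as activated by TAL1 in T-ALL had negative log2 fold changes with dTAG-13 (median -0.21). Of these, 1 fell, ALDH1A2, and 11 did not pass the test; adjusted over the list alone, 5 fell. The camera adjusted p was 1.43e-08, and the adjusted p = 0.227 with an estimated correlation. Members short of the threshold included TSPAN7 (-0.46, SE 0.09), SIX6 (-0.53, SE 0.11), MYB (-0.25, SE 0.08) and RUNX1 (-0.22, SE 0.10), while GATA3 stood at -0.05 (SE 0.08). DESeq2 called TSPAN7 (adjusted p = 0.00995) and SIX6 (adjusted p = 0.0492) lower. All 10 E-protein-associated thymocyte genes had positive values (median 0.38), with 0 called by edgeR over all genes and 6 higher when adjusted over the list alone (camera adjusted p = 1.43e-08; adjusted p = 0.054 with an estimated correlation). RAG1 and RAG2, which encode the recombinase that assembles antigen receptor genes, stood at 0.91 (SE 0.13, adjusted p = 0.0509) and 0.61 (SE 0.11, adjusted p = 0.147), and PTCRA, the pre-T cell receptor alpha chain, at 1.19 (SE 0.19, adjusted p = 0.0909). These were the 3 genes that DESeq2 called higher, RAG1 at an adjusted p of 9.15e-06, RAG2 at 0.00955 and PTCRA at 0.0316. RAG1, RAG2, PTCRA, TSPAN7 and SIX6 also passed in edgeR without the filter on low counts and in a fit of the 4 compared libraries alone.

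The GIMAP family, small GTPases of lymphocytes, had 6 of 7 members negative with dTAG-13 (median -0.38); 0 passed the edgeR test over all genes and 6 were lower adjusted over the list alone (camera adjusted p = 3.36e-08; adjusted p = 0.054 with an estimated correlation). GIMAP1 stood at -0.55 (SE 0.11) and GIMAP4 at -0.39 (SE 0.09). Of the 28 lists tested, 4 others passed camera with smaller medians. Cholesterol synthesis and uptake (0.09, adjusted p = 0.00903; adjusted p = 0.348 with an estimated correlation) and mitochondrially encoded transcripts (0.12, adjusted p = 0.0179; adjusted p = 0.374 with an estimated correlation) were higher. T cell receptor signalling (-0.08, adjusted p = 0.0237; adjusted p = 0.308 with an estimated correlation) and immediate early genes (-0.08, adjusted p = 0.0358; adjusted p = 0.348 with an estimated correlation) were lower. NOTCH1 targets did not pass (median -0.10, adjusted p = 0.141). DTX1, a NOTCH-induced ubiquitin ligase, went from 146 ± 11.8 to 102 ± 3.57 CPM (-0.52, SE 0.09, adjusted p = 0.146). DESeq2 called it lower (adjusted p = 0.00914), as did edgeR without the filter on low counts or with the 4 compared libraries alone. HES1 (-0.42, SE 0.16), MYC (0.02, SE 0.09) and IL7R (-0.03, SE 0.10) did not pass.

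Leaving out any 1 of the 4 libraries, DMSO replicate 1, DMSO replicate 2, dTAG-13 replicate 1 or dTAG-13 replicate 2, ended the calls of PLCH1, CD40LG and ALDH1A2, with adjusted p-values between 0.123 and 0.409 and log2 fold changes between -1.13 and -0.73. Without DMSO replicate 1, 2 genes with clone names, AL161626.1 (2.32) and AC079949.1 (2.52), passed as higher instead; they are named after their values were seen.

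The comparison of GSI with DMSO asks which transcripts respond to blocking gamma-secretase. Transcripts of the NOTCH pathway were among those that fell: DTX1 fell from 146 ± 11.8 to 18.6 ± 0.36 CPM (log2 fold change -2.97, SE 0.10, adjusted p = 2.06e-08) and HES4 from 69.5 ± 9.68 to 12.1 ± 3.83 CPM (-2.53, SE 0.18, adjusted p = 1.86e-05). HES1 fell from 12.7 ± 0.0274 to 2.84 ± 0.627 CPM (-2.16, SE 0.18, adjusted p = 5.71e-05) and NOTCH3 from 84.2 ± 3.94 to 21.5 ± 3.15 CPM (-1.97, SE 0.15, adjusted p = 3.23e-05). HES1 and HES4 encode transcriptional repressors induced by NOTCH. TNFRSF4, the costimulatory receptor OX40 (-3.78, SE 0.21, adjusted p = 1.75e-06), and SH3TC1 (-2.28, SE 0.09, adjusted p = 6.55e-08) fell. So did ID1, an inhibitor of basic helix-loop-helix factors (-1.95, SE 0.18, adjusted p = 1.03e-04), and MYO7B, a myosin at 1633 CPM in DMSO (-1.70, SE 0.11, adjusted p = 5.8e-06). Among the increases were the constant segment and a variable segment of the T cell receptor alpha chain, TRAC (80.4 ± 3.3 to 212.6 ± 15.5 CPM, 1.40, SE 0.11, adjusted p = 2.38e-05) and TRAV8-4 (1.26, SE 0.10, adjusted p = 2.79e-05). PTGDR2, a prostaglandin D receptor (1.56, SE 0.18), LGALS1, a galectin (1.33, SE 0.18), PLCH1 (1.25, SE 0.11), the nuclear receptor RORB (1.15, SE 0.18), ARHGAP39 (1.13, SE 0.16) and the ETS factor ETV5 (1.10, SE 0.18) also rose, with adjusted p-values between 6.71e-05 and 0.0107.

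edgeR's quasi-likelihood test called 137 genes higher and 135 lower with GSI, of which 22 and 41 changed at least 2-fold. In the list of NOTCH1 targets, 12 of 18 measured genes fell, 0 rose and 6 did not pass (median -1.19, camera adjusted p = 1.12e-16; adjusted p = 0.02 with an estimated correlation); adjusted over the list alone, 13 fell and 1 rose. MYC, the oncogenic growth regulator, fell from 344.7 ± 6.46 to 179.9 ± 13.9 CPM (-0.94, SE 0.09). RHOU (-1.35, SE 0.09), PTCRA (-1.59, SE 0.25) and IL7R, the interleukin 7 receptor (-0.46, SE 0.10), fell too. NOTCH1 itself (0.20, SE 0.08, adjusted p = 0.288) and NRARP, at a mean under 1 CPM, did not pass. In the GIMAP family 5 of 7 fell, 7 adjusted over the list alone (median -0.73, camera adjusted p = 3.72e-10; adjusted p = 0.0356 with an estimated correlation). The called members included GIMAP5 at -1.05 (SE 0.09), GIMAP4 at -0.78 (SE 0.09) and GIMAP7 at -0.73 (SE 0.10). These were the 2 of 28 lists that also passed with an estimated correlation.

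Some genes of the TAL1 circuit rose with GSI. Of the 12 genes reported as activated by TAL1, 4 rose, 0 fell and 8 did not pass (median 0.20, camera adjusted p = 0.00832; adjusted p = 0.418 with an estimated correlation), and 6 rose adjusted over the list alone. They were ARID5B (0.74, SE 0.11, adjusted p = 0.00403), RUNX1 (0.52, SE 0.10, adjusted p = 0.0166), GATA3 (0.47, SE 0.08, adjusted p = 0.0126) and TAL1 (0.34, SE 0.08, adjusted p = 0.0486, from 160 ± 9.04 to 202.9 ± 6.84 CPM). The TAL1 complex and core circuit list shares 4 of these 12 genes; 3 of its 10 measured members rose, the same RUNX1, GATA3 and TAL1, and 4 adjusted over the list alone (median 0.18, adjusted p = 0.00832; adjusted p = 0.321 with an estimated correlation). ALDH1A2 (0.38, SE 0.10, adjusted p = 0.11) and MYB (0.05, SE 0.08) did not pass.

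All 24 ribosome biogenesis genes had negative values with GSI (median -0.36, camera adjusted p = 1.33e-10; adjusted p = 0.418 with an estimated correlation). Of these, 2 fell over all genes tested, the RNA polymerase I subunit POLR1B (-0.49, SE 0.09) and MYBBP1A (-0.53, SE 0.10), and 19 adjusted over the list alone. All 25 cytosolic ribosomal protein genes were negative (median -0.18, adjusted p = 0.00141; adjusted p = 0.54 with an estimated correlation), with 0 members called by edgeR over all genes or over the list alone. Their median difference of GSI from DMSO was -0.471 between the libraries numbered 1 and 0.0845 between those numbered 2. Heat shock proteins (median -0.16, adjusted p = 0.00826; adjusted p = 0.497 with an estimated correlation) and amino acid stress response genes (-0.16, adjusted p = 0.00826; adjusted p = 0.467 with an estimated correlation) were also lower as lists, with no member called. Mitosis genes were higher as a list (median 0.22, adjusted p = 8.17e-06; adjusted p = 0.321 with an estimated correlation), 9 adjusted over the list alone and 0 by edgeR over all genes. CENPF stood at 0.33 (SE 0.09) and MKI67, named after its value was seen, at 0.31 (SE 0.09). Cholesterol synthesis and uptake (0.17, adjusted p = 5.71e-04; adjusted p = 0.321 with an estimated correlation), lysosome and autophagy (0.11, adjusted p = 0.0404; adjusted p = 0.418 with an estimated correlation) and replication-dependent histones (0.55, adjusted p = 0.0404; adjusted p = 0.321 with an estimated correlation) were higher. The only member called among these 3 lists was the histone HIST1H2AC (1.88, SE 0.32), whose reads can be shared with other histone genes.

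Several lists did not pass as a whole but held called genes with GSI. The cyclin-dependent kinase inhibitors CDKN2D (0.75, SE 0.11, adjusted p = 0.00541) and CDKN2C (0.40, SE 0.09, adjusted p = 0.0486) rose. Of the T cell receptor signalling list, PTPRC, the phosphatase CD45, rose (0.79, SE 0.08, adjusted p = 4.32e-04), as did CD2 (0.50, SE 0.10), and CD7 fell (-0.57, SE 0.10). CD69, an early activation antigen (0.93, SE 0.17), FAS, the death receptor (0.57, SE 0.10), and XBP1, a secretory stress factor (0.40, SE 0.08), rose, and ID3, an inhibitor of E proteins, fell (-0.60, SE 0.12). S phase genes (median 0.03, adjusted p = 0.583) and glycolysis genes (-0.02, adjusted p = 0.582) did not pass.

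Leaving out 1 library changed the counts for GSI most when it was a control: 20 genes higher and 32 lower passed without DMSO replicate 1, 9 and 23 without DMSO replicate 2, 76 and 67 without GSI replicate 1, and 107 and 125 without GSI replicate 2. Of 40 called genes chosen by the rule for named genes, some passed whichever of the 4 compared libraries was left out. They were PTGDR2, TRAC, TRAV8-4, PLCH1, TNFRSF4, DTX1, HES4, SH3TC1, HES1, NOTCH3, ID1, MYO7B, MYC, RHOU, GIMAP5, GIMAP4 and PTPRC. LGALS1 did not pass without DMSO replicate 2 (adjusted p = 0.115). Without either DMSO library, RORB, ARHGAP39, GATA3, ARID5B, PTCRA, GIMAP7 and CDKN2D did not pass (adjusted p from 0.0564 to 0.274). ETV5, RUNX1, ID3, MYBBP1A, CD7, FAS and HIST1H2AC did not pass without DMSO replicate 1, DMSO replicate 2 or GSI replicate 1 (0.061 to 0.344). IL7R, CD2, XBP1 and CD79A did not pass without DMSO replicate 1, DMSO replicate 2 or GSI replicate 2 (0.0671 to 0.391), and TAL1, POLR1B, CDKN2C and CD69 without any 1 of the 4 (0.0577 to 0.519). TAL1 did not pass with DESeq2's size factors either (0.0543), nor in a fit of the 4 compared libraries alone (0.101).

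The combination against DMSO gives the joint response to both drugs. NOTCH pathway genes again showed large decreases: DTX1 fell to 18.4 ± 1.95 CPM (log2 fold change -2.99, SE 0.10, adjusted p = 1.93e-08) and HES1 to 1.8 ± 0.505 CPM (-2.82, SE 0.20, adjusted p = 1.27e-05). HES4 (-2.30, SE 0.18, adjusted p = 2.29e-05) and NOTCH3 (-1.69, SE 0.15, adjusted p = 9.51e-05) also fell. TNFRSF4 (-3.24, SE 0.20), ADCYAP1, a neuropeptide (-2.23, SE 0.17), ID1 (-1.98, SE 0.18) and MYO7B (-1.52, SE 0.11) fell, with adjusted p-values between 4.92e-06 and 9.51e-05. RAG1 rose from 26 ± 0.853 to 58.6 ± 9.99 CPM (1.17, SE 0.13, adjusted p = 6.37e-04). PTGDR2 (1.58, SE 0.18), LGALS1 (1.28, SE 0.18), EVI2A (1.13, SE 0.16), ARHGAP39 (1.12, SE 0.16), NT5E, the ectonucleotidase CD73 (1.12, SE 0.15), TRAC (1.05, SE 0.10) and TRAV8-4 (1.0, SE 0.10) rose, with adjusted p-values between 1.6e-04 and 0.00364. edgeR called 85 genes higher and 120 lower.

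With the combination, 6 of 7 GIMAP genes fell over all genes and adjusted over the list alone (median -1.11, camera adjusted p = 7.02e-13; adjusted p = 0.0217 with an estimated correlation). GIMAP5 fell from 96 ± 2.41 to 35.6 ± 1.92 CPM (-1.43, SE 0.09), and GIMAP4 also fell (-1.20, SE 0.09). NOTCH1 targets had 12 of 18 lower and 0 higher, 13 lower adjusted over the list alone (median -0.92, adjusted p = 1.21e-16; adjusted p = 0.0201 with an estimated correlation). MYC (-0.70, SE 0.09), RHOU (-1.21, SE 0.09) and IL7R (-0.49, SE 0.10) fell, while PTCRA did not pass (-0.81, SE 0.23, adjusted p = 0.131). Of the 10 E-protein-associated thymocyte genes, 4 rose, among them RAG1, RAG2 (0.85, SE 0.11) and the chemokine receptor CXCR4 (0.42, SE 0.08), the last named after its value was seen. Adjusted over the list alone, 4 rose and 1 fell (median 0.35, adjusted p = 0.00968; adjusted p = 0.21 with an estimated correlation). The list of genes reported as activated by TAL1 did not pass (median -0.17, adjusted p = 0.344). SIX6 (-0.69, SE 0.11, adjusted p = 0.00891) and ALDH1A2 (-0.57, SE 0.11, adjusted p = 0.0208) fell. TAL1 (0.31, SE 0.08), GATA3 (0.28, SE 0.08), RUNX1 (0.39, SE 0.10) and ARID5B (0.40, SE 0.11) did not pass with edgeR, and DESeq2 called RUNX1 higher.

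Of the other lists with the combination, ribosome biogenesis had all 24 genes negative (median -0.33, adjusted p = 7.63e-11; adjusted p = 0.386 with an estimated correlation). POLR1B (-0.55, SE 0.09) and MYBBP1A (-0.52, SE 0.10) fell, and 17 adjusted over the list alone. Cholesterol synthesis and uptake (0.17, adjusted p = 6.24e-06; adjusted p = 0.175 with an estimated correlation), mitosis (0.15, adjusted p = 2.09e-05; adjusted p = 0.258 with an estimated correlation) and histones (0.52, adjusted p = 0.0113; adjusted p = 0.21 with an estimated correlation) were higher as lists. Adjusted over the list alone, 8, 2 and 1 of their genes rose, and over all genes 1 rose, the mitotic kinase TTK (0.40, SE 0.08). Heat shock proteins (-0.17, adjusted p = 0.00134; adjusted p = 0.488 with an estimated correlation) and cytosolic ribosomal proteins (-0.12, adjusted p = 0.0419; adjusted p = 0.732 with an estimated correlation) were lower. CDKN2D (0.74, SE 0.11), CDKN2C (0.51, SE 0.09), PTPRC (0.58, SE 0.08) and XBP1 (0.55, SE 0.08) rose, and CD7 (-0.62, SE 0.10) and the interferon-induced OAS2 (-0.57, SE 0.09) fell.

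Without DMSO replicate 1, 15 genes passed as higher and 39 as lower with the combination; without DMSO replicate 2 the counts were 9 and 29, without combination replicate 1 they were 36 and 59, and without combination replicate 2 they were 103 and 155. Of 36 called genes chosen by the rule, some passed whichever of the 4 compared libraries was left out. They included RAG1, DTX1, HES1, HES4, ADCYAP1, MYC, GIMAP5, GIMAP4, GIMAP7, PTGDR2, TRAC and TRAV8-4. NT5E did not pass without DMSO replicate 1 (adjusted p = 0.0601), LGALS1 and RAG2 without DMSO replicate 2 (up to 0.134). The same held for EVI2A, ARHGAP39, CDKN2D, PTPRC and XBP1 without either DMSO library (up to 0.168), and CDKN2C without DMSO replicate 2 or combination replicate 1 (up to 0.368). SIX6, POLR1B, MYBBP1A, TTK, CD7 and OAS2 did not pass without DMSO replicate 1, DMSO replicate 2 or combination replicate 1 (up to 0.451). ALDH1A2 did not pass without DMSO replicate 1, DMSO replicate 2 or combination replicate 2 (up to 0.264), and IL7R and CD79A without any 1 of the 4 (up to 0.468).

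The combination against dTAG-13 gives the response to GSI in cells that also received dTAG-13. TNFRSF4 (log2 fold change -3.51, SE 0.19, adjusted p = 1.56e-06), HES4 (-2.60, SE 0.18, adjusted p = 1.18e-05), DTX1 (-2.47, SE 0.10, adjusted p = 1.69e-07), HES1 (-2.39, SE 0.20, adjusted p = 5.52e-05) and PTCRA (-2.0, SE 0.21, adjusted p = 3.99e-04, from 9.37 ± 1.19 to 2.33 ± 0.719 CPM) fell. TRAV8-4 (1.55, SE 0.10), TRAC (1.41, SE 0.11), PTGDR2 (1.32, SE 0.17) and TOX2, an HMG-box factor (1.29, SE 0.19), rose, with adjusted p-values between 7.37e-06 and 0.00569. edgeR called 100 genes higher and 89 lower. NOTCH1 targets had 11 of 18 lower and 0 higher, and 13 lower and 2 higher adjusted over the list alone (median -1.08, camera adjusted p = 1.73e-14; adjusted p = 0.0263 with an estimated correlation). NOTCH3 (-1.97, SE 0.15), MYC (-0.72, SE 0.09) and RHOU (-1.20, SE 0.09) fell. IL7R did not pass with edgeR (-0.46, SE 0.10, adjusted p = 0.0515) and was called lower by DESeq2. In the GIMAP family 4 of 7 fell, 5 adjusted over the list alone (median -0.74, adjusted p = 4.89e-09; adjusted p = 0.0447 with an estimated correlation), led by GIMAP5 (-1.08, SE 0.09).

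Of the genes reported as activated by TAL1, 3 of 12 rose with the combination against dTAG-13 and 5 adjusted over the list alone (median 0.20, adjusted p = 0.00595; adjusted p = 0.331 with an estimated correlation). These were RUNX1 (0.61, SE 0.10, adjusted p = 0.00836), ARID5B (0.61, SE 0.11, adjusted p = 0.0161) and TAL1 (0.44, SE 0.08, adjusted p = 0.0178). The overlapping core circuit list had 2 of 10 higher, and 4 adjusted over the list alone (median 0.11, adjusted p = 0.00916; adjusted p = 0.331 with an estimated correlation). All 24 ribosome biogenesis genes were negative (median -0.35, adjusted p = 1.13e-11; adjusted p = 0.331 with an estimated correlation). POLR1B (-0.47, SE 0.09) and MYBBP1A (-0.51, SE 0.10) fell, and 21 adjusted over the list alone. Cytosolic ribosomal proteins (-0.21, adjusted p = 5.68e-04; adjusted p = 0.696 with an estimated correlation), heat shock proteins (-0.20, adjusted p = 4.17e-04; adjusted p = 0.411 with an estimated correlation) and oxidative phosphorylation (-0.11, adjusted p = 0.0407; adjusted p = 0.71 with an estimated correlation) were lower as lists. Cell cycle inhibitors and D cyclins (0.20, adjusted p = 0.025), cholesterol synthesis (0.12, adjusted p = 0.00916), mitosis (0.10, adjusted p = 0.0064) and lysosome genes (0.05, adjusted p = 0.0317) were higher, each with adjusted p = 0.331 with an estimated correlation. CDKN2D (0.83, SE 0.11), PTPRC (0.75, SE 0.08), XBP1 (0.44, SE 0.08) and BCL2, the survival factor (0.58, SE 0.11), rose, and CD7 fell (-0.52, SE 0.10).

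For this comparison 35 genes higher and 41 lower passed without dTAG-13 replicate 1, 14 and 29 without dTAG-13 replicate 2, 44 and 52 without combination replicate 1, and 118 and 146 without combination replicate 2; a fit of the 4 compared libraries alone gave 47 and 49. Of 25 called genes chosen by the rule, some passed whichever of the 4 compared libraries was left out. They included TNFRSF4, HES4, DTX1, HES1, PTCRA, MYC, TRAC, TRAV8-4, PTGDR2, GIMAP5, CDKN2D and PTPRC. TOX2 and GIMAP7 did not pass without dTAG-13 replicate 2 (adjusted p up to 0.116), nor RUNX1 without either dTAG-13 library (up to 0.175). Nor did ARID5B without dTAG-13 replicate 2 or combination replicate 1 (up to 0.26), XBP1 without either dTAG-13 library or combination replicate 2 (up to 0.255). TAL1, POLR1B, MYBBP1A, BCL2 and CD7 did not pass without either dTAG-13 library or combination replicate 1 (up to 0.345).

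**Figure D2:**
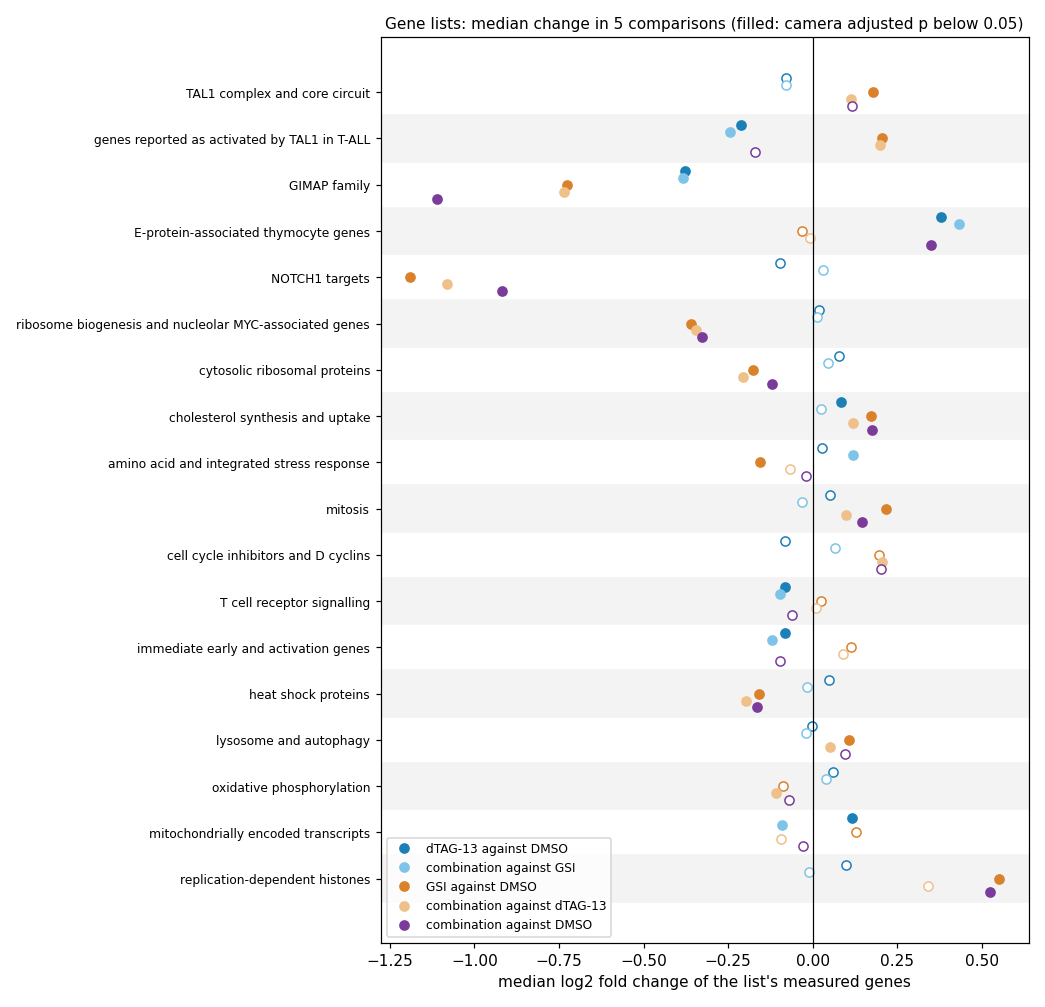
Each point is the median log2 fold change of the measured genes of 1 list in 1 of 5 comparisons, for the 18 lists that passed camera in at least 1 of them; filled points passed with a preset correlation and open points did not. NOTCH1 targets lay at -1.19 with GSI against DMSO, and E-protein-associated thymocyte genes lay at 0.38 with dTAG-13 against DMSO and at 0.43 with the combination against GSI.

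The combination against GSI gives the response to dTAG-13 in cells treated with GSI. RAG1 rose from 21.4 ± 3.66 to 58.6 ± 9.99 CPM (log2 fold change 1.45, SE 0.13, adjusted p = 6.96e-04), SH3TC1 from 25.6 ± 0.394 to 44.8 ± 1.9 CPM (0.81, SE 0.09, adjusted p = 0.00397) and RAG2 from 35.3 ± 1.87 to 58 ± 2.29 CPM (0.72, SE 0.11, adjusted p = 0.0465). PLCH1 fell from 26.6 ± 1.03 to 11.7 ± 0.28 CPM (-1.18, SE 0.11, adjusted p = 6.96e-04), CD40LG from 68.4 ± 0.797 to 34 ± 2.08 CPM (-1.01, SE 0.09, adjusted p = 6.96e-04) and ALDH1A2 from 174.3 ± 21.4 to 90.4 ± 10.9 CPM (-0.95, SE 0.11, adjusted p = 0.00397). GZMA, a granzyme (-1.11, SE 0.16, adjusted p = 0.0284), and the keratin KRT1 (-1.08, SE 0.14, adjusted p = 0.0104) also fell. With RP5-1028K7.2, a clone-named gene outside the rule for named genes (-1.10), these make the 3 genes higher and 6 lower that edgeR called. The 3 genes lower with dTAG-13 against DMSO were all among them, in a comparison that uses none of the same libraries. Independent lists of these sizes would share 0.00115 genes. That value is not a level of chance, since both comparisons share 1 fit and its estimate of each gene's spread. In a fit of the 4 compared libraries alone, ALDH1A2 did not pass in the combination against GSI.

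In cells treated with GSI, 9 of 10 E-protein-associated thymocyte genes were positive with dTAG-13, 2 rose, RAG1 and RAG2, and 7 adjusted over the list alone (median 0.43, camera adjusted p = 9.83e-09; adjusted p = 0.0784 with an estimated correlation). All 12 genes reported as activated by TAL1 were negative, ALDH1A2 was called, and 6 were lower adjusted over the list alone (median -0.24, adjusted p = 3.01e-08; adjusted p = 0.189 with an estimated correlation). GIMAP genes were negative in 6 of 7 cases, with 0 called by edgeR over all genes and 4 lower adjusted over the list alone (median -0.38, adjusted p = 1.35e-05; adjusted p = 0.112 with an estimated correlation). DESeq2 called GIMAP1 of this family and TSPAN7 of the genes reported as activated by TAL1 lower. T cell receptor signalling (-0.10, adjusted p = 0.00284; adjusted p = 0.189 with an estimated correlation), immediate early genes (-0.12, adjusted p = 0.0293; adjusted p = 0.382 with an estimated correlation) and mitochondrially encoded transcripts (-0.09, adjusted p = 0.0293; adjusted p = 0.545 with an estimated correlation) were lower, and amino acid stress response genes (0.12, adjusted p = 0.00107; adjusted p = 0.545 with an estimated correlation) were higher. RAG1, SH3TC1, PLCH1, CD40LG and ALDH1A2 passed whichever of the 4 libraries was left out; KRT1 did not pass without combination replicate 1 or 2 (adjusted p up to 0.112), nor RAG2 and GZMA without any 1 of the 4, GSI replicate 1 and GSI replicate 2 included (up to 0.268). Without combination replicate 2 the genes lower numbered 3, and a fit of the 4 compared libraries alone called 1 higher and 2 lower, with RAG2 (0.117), GZMA (0.0991), SH3TC1 and KRT1 (both 0.0887) and ALDH1A2 not passing.

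The test of departure from additivity asks whether the effect of dTAG-13 differed with and without GSI. edgeR's quasi-likelihood test called 0 genes higher and 0 lower, and DESeq2 also called 0. With edgeR 260 genes, 1.66% of those tested, had an unadjusted p below 0.05, a share that unchanged genes alone could give. DTX1 (0.50, SE 0.14), MYC (0.22, SE 0.12), RAG1 (0.54, SE 0.19) and PTCRA (-0.41, SE 0.34) did not pass. For DTX1 the SE was 0.09 with dTAG-13 against DMSO, so the departure was measured less precisely. The simulations did not cover this test, and 0 calls do not show that the effects add up. Without DMSO replicate 1, AC079949.1, named after its value was seen, passed as lower (-2.53, adjusted p = 0.00154); it stood at 4.77 CPM in DMSO replicate 2 and at 25.2 to 29 CPM in the other 7 libraries. The effect of GSI was alike in sign with and without dTAG-13. Of the 272 genes called against DMSO, 270 had the same sign in the combination against dTAG-13, which uses other libraries. In both comparisons 83 were called higher and 75 lower, against 0.876 and 0.768 for independent lists of these sizes. These last values are not levels of chance, since both comparisons share 1 fit and its estimate of each gene's spread.

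Against the shared DMSO libraries, 0 genes were called in the same direction with dTAG-13 and with GSI by edgeR, where independent lists would give 0.0259 lower in both. At an unadjusted p below 0.05, 601 genes (3.84%) passed with dTAG-13 and 2197 (14%) with GSI. Unchanged genes alone could give the share with dTAG-13, which rests on a spread pooled over all 4 groups. DESeq2 called 2 genes in the same direction. PLCH1 was called in opposite directions, lower with dTAG-13 and higher with GSI. The log2 fold changes of both comparisons correlated across genes at 0.297 (Spearman 0.209), where 10 simulations of unchanged groups against the same controls gave 0.517; genes are not independent replicates. Their covariance was 0.0301, against a simulated 0.0335 (SD 8.81e-04). For the combination and GSI, 51 genes were called higher and 82 lower in both, against 0.744 and 1.04 for independent lists, with a covariance of 0.0845 against a simulated 0.0332 (SD 0.00127). The 2 DMSO libraries were not divided between the comparisons, since each part would hold 1 library, and part of these overlaps may come from the shared controls.

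In the authors' deposited table of dTAG-13 against DMSO, 6 genes were higher and 26 lower at the same adjusted threshold. The 3 edgeR calls were among these 32. In the authors' deposited table of GSI against DMSO, 113 were higher and 130 lower, and 204 of those were also called by edgeR. In the authors' deposited table of the combination against DMSO, 80 were higher and 113 lower, of which 158 were shared. All shared calls had the same sign, and the log2 fold changes correlated across genes at 0.999.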

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

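The length and GC offset, the crossed block and the averages over both backgrounds were chosen after the results were seen; the other settings were planned. Leaving out a library leaves a lone sample, which is assumed to vary like the other groups. Counts are given as genes higher and lower.

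With no filter on low counts, dTAG-13 against DMSO had 11 and 40, GSI against DMSO 303 and 357, the combination 244 and 288 against DMSO, 264 and 299 against dTAG-13, and 14 and 45 against GSI. With DESeq2, dTAG-13 had 3 and 18 and the combination against GSI 5 and 15. Fitting the 4 compared libraries alone gave 12 and 59 for dTAG-13, 47 and 49 for the combination against dTAG-13, and 1 and 2 against GSI. The length and GC offset gave 1 and 5 for dTAG-13, 135 higher for the combination against DMSO, 168 and 140 against dTAG-13, 10 lower against GSI, and 21 higher for averaged dTAG-13.

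Samples share only a replicate number, and the labels do not pair them. With a replicate block, dTAG-13 had 3 (RAG1, RAG2 and PTCRA, adjusted p = 0.00134 to 0.0201) and 20 (among them DTX1 at 0.0311 and TSPAN7 and SIX6 at 0.0461), GSI 264 and 295, and the combination 182 and 231 against DMSO, 241 and 235 against dTAG-13, and 6 and 28 against GSI (the 28 include GIMAP1 at -0.70, adjusted p = 0.0189, and TSPAN7 at -0.44, adjusted p = 0.0432). The dTAG-13 effect averaged over both backgrounds had 28 and 107 and the GSI effect 858 and 964. Block and offset together gave 6 and 29, 368 and 430, 264 and 332, 311 and 333, and 9 and 33 in that order. Replicate differences correlated across genes at 0.138 to 0.214 among dTAG-13, GSI and the combination, and at -0.108 to -0.0304 between DMSO and these 3. A block with the DMSO numbers crossed gave 716 and 865 for GSI against DMSO, 79 and 204 for averaged dTAG-13, and 1453 and 1768 for averaged GSI. This block was picked from these same libraries, so its larger counts can follow from that choice alone. Genes called in the same direction with dTAG-13 and GSI against DMSO numbered 2 with DESeq2 and 4 with the block, and those in opposite directions 8 and 12.

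Leaving out 1 library gave 0 to 2 higher and 0 to 0 lower for dTAG-13, 9 to 107 and 23 to 125 for GSI, and for the combination 9 to 103 and 29 to 155 against DMSO, 14 to 118 and 29 to 146 against dTAG-13, and 2 to 3 and 3 to 5 against GSI. For the departure it gave 0 to 0 higher and 0 to 1 lower. Of 112 called results of named genes, 0 changed sign in any of these alternatives. All were already called, and the highest and lowest genes were chosen with groups that do not overlap. A change of sign was therefore unlikely from the start. DESeq2's size factors ended 2 of the calls, TAL1 (adjusted p = 0.0543) and CDKN2C with GSI against DMSO. The fit of 4 libraries ended 14, among them TAL1 with GSI (adjusted p = 0.101) and, for the combination against GSI, SH3TC1 and KRT1 (adjusted p = 0.0887 each), RAG2 (0.117), GZMA (0.0991) and ALDH1A2.

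Of the lists that passed camera, 6 of 7 also passed with the replicate block for dTAG-13 against DMSO, 12 of 12 for GSI against DMSO, 9 of 9 for the combination against DMSO, 12 of 12 against dTAG-13, where 1 more passed, and 6 of 7 against GSI. The list that did not was immediate early genes, with dTAG-13 against DMSO (adjusted p = 0.093) and with the combination against GSI (adjusted p = 0.0907). With fry, 2, 6, 6, 3 and 2 of the lists also passed in that order.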

Other observations

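The averages over both backgrounds, the low oxygen test, the share of variance taken by length and GC, the test of exchanged DMSO numbers and the block with these numbers crossed were chosen after the results were seen. Averaging the effect of dTAG-13 over cells with and without GSI, edgeR called 12 genes higher and 66 lower. Of the 10 E-protein-associated thymocyte genes 4 rose, among them RAG1 (log2 fold change 1.18, SE 0.09), RAG2 (0.66, SE 0.08) and PTCRA (0.98, SE 0.17) (camera adjusted p = 1.99e-11; adjusted p = 0.0494 with an estimated correlation). Of the 12 genes reported as activated by TAL1 4 fell, among them ALDH1A2 (-0.88, SE 0.08), SIX6 (-0.49, SE 0.08) and TSPAN7 (-0.45, SE 0.06) (camera adjusted p = 1.99e-11; adjusted p = 0.0992 with an estimated correlation). GIMAP4 fell (-0.40, SE 0.06). STAT5A, a cytokine-activated transcription factor (-0.64, SE 0.09), SPRY4 (-1.32, SE 0.20), SPRED2 (-0.40, SE 0.06), ETV5 (-0.84, SE 0.14) and EGR1 (-1.51, SE 0.26) also fell; these 5 genes are named after their values were seen.

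Averaged likewise, GSI had 529 genes higher and 557 lower, and 49 genes were called for both drugs. Of these, 34 were lower with dTAG-13 and higher with GSI, where independent lists would give 2.23. Another 8 were lower with both (2.35), 4 higher with dTAG-13 and lower with GSI (0.427), and 3 higher with both (0.406). The values for independent lists are not levels of chance, since both averages share 1 fit and its estimate of each gene's spread. PLCH1 was at -1.15 with dTAG-13 and 1.22 with GSI, SPRY4 at -1.32 and 1.07, and CD69 at -0.76 and 0.72. PTCRA (0.98 and -1.80) and SH3TC1 (0.57 and -2.04) went the other way, and GIMAP5 fell with both (-0.37 and -1.06). The exact test of direction among the 49 genes gave a 2-sided Fisher p of 0.0513. That p treats the genes as independent, though all were measured in the same 8 libraries, so it does not measure the spread between samples. The effects correlated across all genes at -0.0864 (Spearman -0.113). The GSI counts fell when either DMSO library, either dTAG-13 library, GSI replicate 1 or combination replicate 1 was left out. They rose without GSI replicate 2 and without combination replicate 2.

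The genes called for averaged dTAG-13 were set against 3 technical explanations. Thinning every library to the smallest total kept 67 of the 78, and the length and GC offset kept 77, which argues against depth and those trends as the whole cause. The splits of the libraries do not exclude chance: 2 of 34 splits of the libraries into 4 and 4 called as many genes as the real 119 in a model with only GSI and split terms, the other calling 1471. That split puts DMSO replicate 1 with replicate 2 of the other 3 groups. A count so far above the real one points to a structure of the samples. With that structure as a block, 79 genes were higher and 204 lower. The block was picked from these same libraries and takes up their spread. Larger counts can follow from that choice alone, so they do not bear on chance. Without DMSO replicate 1 the counts were 5 higher and 9 lower, without DMSO replicate 2 they were 3 and 14, without dTAG-13 replicate 1 or 2 they were 4 and 22 or 4 and 14, without combination replicate 1 they were 7 and 37, without GSI replicate 1 they were 6 and 48, and without combination replicate 2 they were 19 and 59.

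For averaged GSI, 1 of 34 splits, the real one, called 1476 genes and the highest other called 0, a share below 0.05. The GSI effect stays in the residual of the other splits and lowers their counts, so these splits cannot decide whether chance explains the calls. Of 24 ribosome biogenesis genes, 16 fell (median -0.36, adjusted p = 6.98e-13; adjusted p = 0.31 with an estimated correlation), and 0% of 10000 random lists matched on length and GC were as low, which argues against those trends. The highest median among the 4 pairs of libraries with the same number was -0.226, so 1 pair alone does not account for it. For the 25 cytosolic ribosomal proteins (median -0.19, adjusted p = 7.46e-05; adjusted p = 0.592 with an estimated correlation), 0% of matched lists were as low. Their pair medians ran from -0.471 to 0.0845, the last in GSI replicate 2 against DMSO replicate 2, so an uneven contribution of the pairs stays open.

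Replicates of a group differed across genes; the labels give no day or batch, and apart from a low oxygen response no biological explanation was tested. Length and GC took up 5.17% of the variance of the replicate difference in the combination and 22.9% in GSI, which leaves their part open, but the split that crosses the DMSO numbers still called 1107 genes after the offset for them. A list of low oxygen response genes, 22 of 24 measured and 6 also in the fixed lists, had a higher median in replicate 1 of every group (0.204 with DMSO, 0.272 with dTAG-13, 0.236 with GSI and 0.645 with the combination), and 100% of matched random lists lay below it. Random lists were drawn gene by gene, so any set of genes that vary together could lie beyond them. The 100% therefore does not point to low oxygen in particular. Exchanged DMSO replicate numbers stay open. The sign of the low oxygen list in DMSO (0.204) argues against them. But the correlations across genes of the replicate difference with length and GC were -0.13 and 0.227 in DMSO and had the opposite signs in the other 3 groups. A difference in oxygen or density may be part of how replicate 1 and replicate 2 differ, and it cannot be separated from the replicate number. The low oxygen list was higher in replicate 1 of DMSO too, so it does not follow the split that crosses the DMSO numbers.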
